A study of Homo sapiens and Mus musculus with 54 samples.

How the data were processed

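The series holds 54 ChIP-seq libraries, 30 from HepG2 cells and 24 from mice. Libraries were placed in 20 groups by their titles, and 12 of them are inputs. Vitamin B2-deficient and control conditions were compared on day 12 in HepG2 and after 4 weeks in mice, per the labels.

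The authors deposited 6 peak lists, each with 5 columns that give a name, a chromosome, a start, an end and a strand sign. The deposited values are positions, and no list used here carries a tag count, a score or any other value for a library. Bowtie2 and HOMER are named, without versions, per the submitters' processing notes, which also name the builds hg38 and mm10. The peak names have the form HOMER gives to merged peaks and end in a number, read here as the number of peaks merged into the entry and called the merge number. Which peak sets were merged, the caller settings and the filters are not given in the sources used here. The 2 HepG2 H3K27ac lists are called the untreated list and the inhibitor list, after the experiments the deposited lists are named for. The depth of the libraries is unknown here, so no value has a precision set by reads, and the Wilson intervals printed at 95% cover counting error over peaks only. Neighbouring peaks are not independent, so these intervals are too narrow.

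The designs fixed before the data were examined compared the conditions peak by peak and allowed for lists without values per library, in which case peak numbers were to be described with no test of the conditions. That case applied. Every test between B2-deficient and control libraries, between inhibitor and vehicle, and between Ad-Cre and Ad-Cont was therefore left out, along with the set tests on fold changes. Motif content and GC content need a genome and were not analysed here. The tests reported in their place, of overlap and of gene lists, were chosen after the lists had been seen to hold positions alone.

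Peaks were taken to overlap when they shared at least 1 bp. Alternatives were an overlap of 50% of the shorter peak and centres within 500 bp. Each share was set against 1000 random shifts, in which the peaks of a list were moved together round each chromosome. The shifts can place peaks in closed or unmappable sequence, so a share above them may reflect open chromatin common to both lists. Shares of merged peaks (merge number 2 or more) and single peaks (merge number 1) were compared by a two-sided permutation test over chromosomes with 100000 resamples. Within H3K27ac regions, the association of AhR and C/EBPα peaks was given as a Mantel-Haenszel odds ratio over 8 strata of region width and merge class, with a 95% interval from leaving out each chromosome in turn.

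Genes came from the RefSeq table of GRCh38.p14, the assembly of hg38, with 19974 protein-coding genes on chromosomes 1 to 22 and X. The table used here has gene starts and ends without strand, so transcription start sites were not placed. Each peak was assigned to the nearest gene body within 50 kb, in place of the planned nearest start site, and 10 kb and a peak within 1 kb of either gene end were the alternatives. No mouse gene table was used here, so mouse peaks carry no gene names. The 19 gene lists were fixed before the data were examined, and 321 of their 332 distinct symbols were found. For each list, the share of members with a peak was set against 10000 random lists matched on 10 classes of gene length, with a two-sided p and Benjamini-Hochberg adjustment over the 19 lists. A list was called above chance at an adjusted p under 0.05.

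The genes named whatever their value were AHR, AHRR, CYP1A1, CYP1B1 and TIPARP. The rule also asked for the peaks with the highest score, which could not be applied to lists of positions. Other genes named in the text were chosen after their values were seen.

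The routines were tested on simulated data. All 20000 of 20000 simulated peaks received the planted overlap call, and random shifts gave a mean share of 25.2% where 24.9% was expected. Of 200 simulated lists of 20 genes drawn from 19974 genes, 2.0% were called without enrichment and 98.0% were called with a planted share of 95%. These calls used a p under 0.05 without adjustment and fewer random lists than the reported tests. Lists of other sizes were not simulated, so these rates do not describe the adjusted calls or the smaller lists. An odds ratio of 3 was recovered as 2.99. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.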

Results

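Binding of the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor, was profiled by ChIP-seq with the liver factor C/EBPα and with H3K27ac, a histone mark of active enhancers and promoters. HepG2, a human liver cancer cell line, was kept with or without vitamin B2 until day 12. AhR and C/EBPα ChIP each had 2 control and 2 B2-deficient libraries, and H3K27ac had 5 of each. A second H3K27ac experiment had 2 control libraries with DMSO, 2 B2-deficient libraries with DMSO and 2 B2-deficient libraries with an AhR inhibitor. In mice, AhR was profiled in the liver with 3 control and 3 B2-deficient libraries. H3K27ac was profiled in hepatocytes carrying a floxed AhR gene, with 3 libraries for each of the 4 combinations of B2 supply and Ad-Cre or Ad-Cont. The 12 input libraries completed the series, and 2 of them are titled for both the AhR and the C/EBPα ChIP of B2-deficient HepG2. Whether these shared inputs affected the overlap of the AhR and C/EBPα lists was not tested. The peak lists are named for experiments and gave positions without a value per library. The depth is therefore unknown, no difference between conditions was measured, and which conditions contributed to a list is not given in the sources used here.

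The first question was where AhR lay in HepG2. At CYP1A1, the cytochrome P450 gene classically induced through AhR, 5 AhR peaks were assigned and all 5 had a merge number of 2. TIPARP, an AhR-induced ADP-ribosyltransferase, had 8 AhR peaks, AHRR, the AhR repressor, had 4, CYP1B1 had 2, and AHR itself had 1. Of the 5 peaks at CYP1A1 (gene ID 1543, chromosome 15, 74719542 to 74725528 in hg38), 1 lay inside the gene at 74723681 to 74723934. Another 2 lay 406 and 874 bp beyond the gene end at 74725528, at 74725934 to 74726198 and at 74726402 to 74726632, and neither overlapped an H3K27ac region. The untreated H3K27ac list had a step 3 kb from gene ends, with fewer regions on the gene side of it. This absence alone therefore does not show a lack of acetylation. The 2 peaks farther out, at 74716650 to 74716881 and at 74731015 to 74731246, overlapped both a C/EBPα peak and an H3K27ac region. At CYP1A2, the neighbouring P450 gene, 1 of 2 AhR peaks overlapped an H3K27ac region and neither overlapped a C/EBPα peak.

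**Figure D1:**
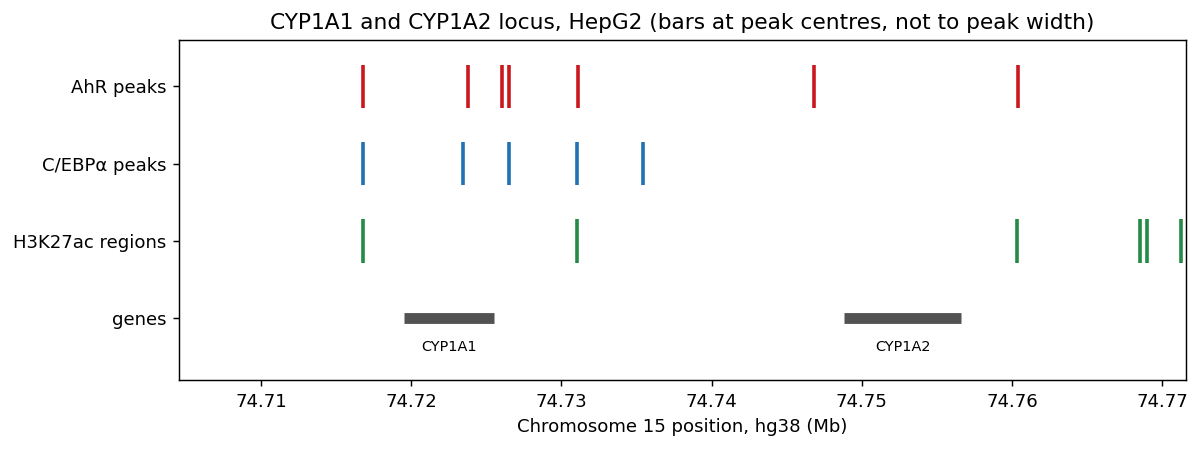
Positions of AhR peaks, C/EBPα peaks and H3K27ac regions (untreated list) in HepG2 around CYP1A1 and CYP1A2 on chromosome 15, in Mb of hg38, with bars at peak centres and gene bodies below. The locus holds 7 AhR peaks, 5 C/EBPα peaks and 6 H3K27ac regions, and the AhR peaks nearest the CYP1A1 gene have no H3K27ac region. The H3K27ac list has a step 3 kb from gene ends, so this absence alone does not show a lack of acetylation.

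The 4 AhR peaks of AHRR (gene ID 57491, chromosome 5, 321714 to 438285) all had a merge number of 1; 3 lay inside the gene and 1, at 321550 to 321786, spanned a gene end. None of the 4 overlapped a C/EBPα peak, and 3 overlapped an H3K27ac region. The AhR peak in AHR (gene ID 196, chromosome 7, 17298652 to 17346147) lay inside the gene at 17307151 to 17307367 and overlapped both a C/EBPα peak and an H3K27ac region. Of the 8 peaks of TIPARP (gene ID 25976, chromosome 3, 156674590 to 156706770), 3 lay inside the gene, 5 overlapped an H3K27ac region and 3 overlapped both. The 2 peaks of CYP1B1 (gene ID 1545, chromosome 2, 38067509 to 38076151) lay 1335 and 20152 bp from the gene and overlapped neither. NQO1, a quinone reductase chosen after its values were seen, had 2 AhR peaks, 1 inside the gene and 1 across a gene end, and no assigned H3K27ac region. The step of the H3K27ac list near gene ends limits the reading of this absence too.

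Across the genome the HepG2 AhR list held 56739 peaks with a median width of 234 bp, of which 42.3% were merged. The C/EBPα list held 62761 peaks with a median width of 231 bp, of which 59.6% were merged. AhR peaks were assigned to 12204 genes, 61.1% of protein-coding genes, and C/EBPα peaks to 13273 genes, 66.5%. Of the AhR peaks on chromosomes 1 to 22 and X, 56.0% lay inside a gene and 85.8% lay more than 3 kb from every gene end. The merge number does not say which conditions or libraries the merged peaks came from.

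The next question was how far AhR sites coincided with C/EBPα sites and with H3K27ac, the enhancer measure named by the design. A C/EBPα peak overlapped 55.3% of AhR peaks (31401 of 56739, 95% Wilson interval 54.9 to 55.8), from 47.2% on chromosome 19 to 61.3% on chromosome 20. Random shifts gave a mean of 1.05%, so the share was 52.6-fold higher (permutation by shifts, one-sided p = 0.001, the smallest that 1000 shifts can give). The shifts do not keep peaks to open chromatin, so this fold does not separate joint binding from open sites used by both factors. An H3K27ac region overlapped 70.7% of AhR peaks (95% Wilson interval 70.3 to 71.0), 34.9-fold above shifts, and 48.7% of C/EBPα peaks (95% Wilson interval 48.4 to 49.1), 23.5-fold above shifts, each again at the smallest p of 0.001. Conversely, an AhR peak lay in 37.8% of H3K27ac regions and a C/EBPα peak in 28.9%.

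AhR peaks with both a C/EBPα peak and an H3K27ac region numbered 23334, 41.1% of the list, and 63.8% of these were merged. A further 16764 (29.5%) had an H3K27ac region alone and 8067 (14.2%) a C/EBPα peak alone. The 8574 AhR peaks with neither (15.1%) were merged in 13.3% of cases, and 19.4% of them lay within 1 kb of a gene end, against 2.02% of the peaks with both. This share was 13.7% with a C/EBPα peak alone and 2.67% with an H3K27ac region alone. Nearness to a gene end thus went mainly with the lack of an H3K27ac region. The untreated H3K27ac list had a step 3 kb from gene ends, with 1.67 times as many regions from 3000 to 3500 bp as from 2500 to 3000 bp (95% interval 1.56 to 1.79), while the same ratio was 0.962 for AhR (95% interval 0.878 to 1.05). Within 1 kb of gene ends that list held 3.78 regions per bp of distance, against 3.84 from 4000 to 5000 bp. Of AhR peaks beyond 3 kb of gene ends, a setting chosen after seeing the data, 77.5% had an H3K27ac region against 70.7% of all. For a C/EBPα peak these shares were 56.3% and 55.3%. What made the step was not tested.

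Merged AhR peaks overlapped a C/EBPα peak more often than single ones, 73.2% against 42.3%, on 23 of 23 chromosomes (mean difference 30.2 ± 3.21 percentage points, SD over chromosomes, permutation p = 2e-05, the smallest the resamples can give). The H3K27ac share was 84.1% in merged and 60.8% in single AhR peaks, also higher on 23 of 23 chromosomes (22.9 ± 4.5 points, SD, permutation p = 2e-05). C/EBPα peaks with merge numbers 1, 2 and 3 held an AhR peak in 27.7%, 43.6% and 76.7% of cases. Within the 106666 H3K27ac regions of the untreated list, an AhR peak was present in 76.4% of regions with a C/EBPα peak and in 22.1% of regions without, an odds ratio of 10.6 (95% interval 10.1 to 11). The strata hold region width and merge class only, so this ratio does not separate joint binding from open sites used by both factors either.

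**Figure D2:**
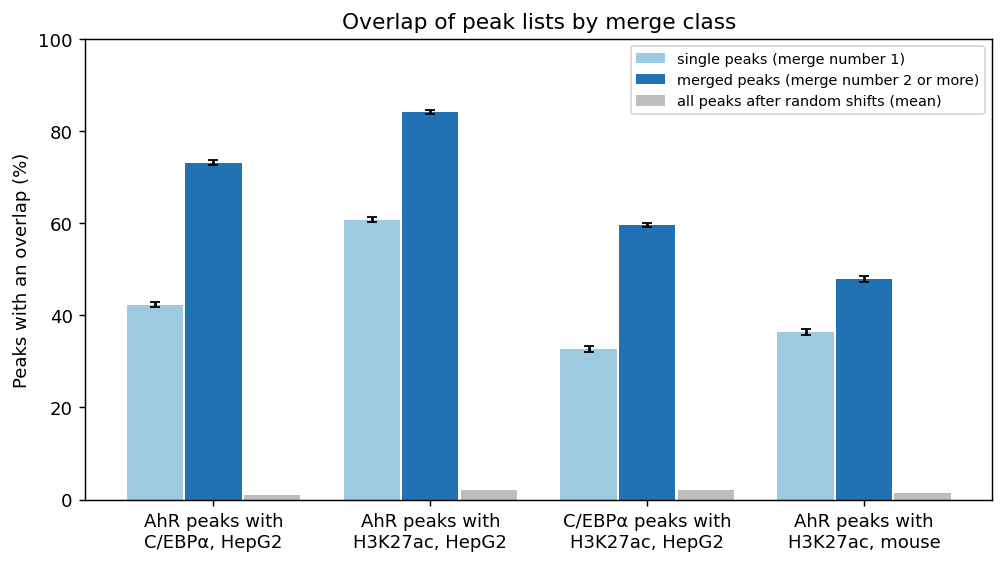
Percent of peaks with an overlap (vertical axis) for single and merged peaks in 4 pairs of lists, with 95% Wilson intervals as error bars, beside the mean after 1000 random shifts of all peaks. Merged peaks lie above single peaks in each pair, as in 73.2% against 42.3% of AhR peaks with a C/EBPα peak.

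AhR centres lay close to the centres of the other lists. Over the 41499 AhR peaks with an H3K27ac region centre within 1000 bp, the median distance was 28 bp, from 26.5 to 32 bp over autosomes. The median distance from an AhR centre to a C/EBPα centre was 24.5 bp. The H3K27ac regions were narrow, with a median width of 284 bp.

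**Figure D3:**
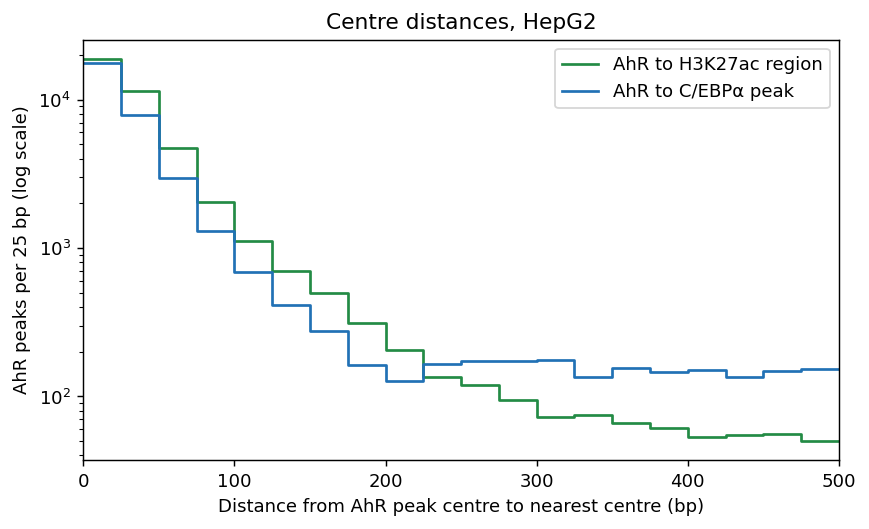
Number of AhR peaks per 25 bp of distance (log scale) against the distance in bp from the AhR peak centre to the nearest H3K27ac region centre or C/EBPα peak centre in HepG2. The counts are highest in the bins nearest 0, and the median distances are 28 and 24.5 bp over pairs within 1000 bp.

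The fixed gene lists were then read for AhR peaks assigned to their genes within 50 kb in HepG2. A peak counted only for its nearest gene, so a gene without a peak may have one nearby that lies nearer another gene. Random lists were matched on length and not on the spacing of genes. All 15 AhR targets, all 26 genes of PPARA and fatty acid oxidation, all 20 NRF2 response genes and all 29 hepatocyte identity genes had an AhR peak, against 59.5%, 61.5%, 61.3% and 53.0% in length-matched random lists (permutation, adjusted p = 0.003, 0.0013, 0.0013 and 0.0013). Counting only peaks within 1 kb of a gene end, the AhR targets were no longer called above chance (permutation, adjusted p = 0.062). They stood at 2.4-fold the random mean against 1.68-fold within 50 kb. Random lists spread wider (middle 95% up to 2.05-fold against 1.34-fold), and the targets lay above that range but did not pass after adjustment. In all, 12 of the 19 lists were above chance and none was below it. Among fatty acid oxidation genes, PPARGC1A, a coactivator of PPARA, had 25 AhR peaks, PLIN2, a lipid droplet coat protein, had 11, and CPT1A, which admits fatty acids to mitochondria, had 6. Among hepatocyte identity genes, ALB had 24, TF had 20, SERPINA1 had 18 and HNF4A had 15. FTH1, the ferritin heavy chain, had 15 and ABCC3, an export pump, had 16 among NRF2 response genes.

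Gluconeogenesis genes held an AhR peak in 14 of 15 cases (permutation, adjusted p = 0.013), with 15 peaks at GPT2, 9 at G6PC1 and 5 at PCK1, and SDS had none. Lipogenesis genes did so in 18 of 19 (permutation, adjusted p = 0.03), with 14 at MLXIPL and 12 at SCD, and bile acid metabolism genes in 16 of 18 (adjusted p = 0.032), with 5 at CYP7A1, the rate-limiting enzyme of bile acid synthesis. The acute phase list had 18 of 22 (permutation, adjusted p = 0.0028), the integrated stress response 18 of 23 (adjusted p = 0.016), the hypoxia response 19 of 21 (adjusted p = 0.017), the p53 response 13 of 15 (adjusted p = 0.029) and cholangiocyte markers 9 of 10 (adjusted p = 0.031). Within the integrated stress response, ATF4, ASNS and DDIT3 had no assigned AhR peak, while TRIB3 had 7 and FGF21 had 5. Matching on the number of H3K27ac regions, chosen after seeing the data, ended the calls for gluconeogenesis (permutation, adjusted p = 0.54, from 1.59-fold the random mean to 1.11-fold), lipogenesis (0.25, 1.35 to 1.14), bile acid metabolism (0.12, 1.4 to 1.27), the integrated stress response (1.0, 1.57 to 1.02), the hypoxia response (1.0, 1.4 to 1.06), the p53 response (1.0, 1.58 to 1.08) and cholangiocyte markers (0.83, 1.7 to 1.17). Other calls were lost without a smaller fold, where random lists spread wider, although lipogenesis still lay above their middle 95% before adjustment. Within 1 kb of a gene end these were lipogenesis (permutation, adjusted p = 0.062, 2.23-fold, middle 95% of random lists up to 1.95-fold), the p53 response (0.15, 2.1-fold, up to 2.1-fold) and cholangiocyte markers (0.52, 1.71-fold, up to 2.28-fold), with merged peaks cholangiocyte markers (0.16, 1.77-fold, up to 1.77-fold), and by the mean number of peaks bile acid metabolism (0.24, 1.42-fold, up to 1.68-fold), where within 50 kb those limits were 1.28, 1.46, 1.51 and 1.31 for the 4 lists.

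Riboflavin handling genes had an AhR peak in 6 of 9 cases against 53.8% in random lists (permutation, adjusted p = 0.69). RFK, which makes FMN from riboflavin, had 1 AhR peak, and FLAD1, which makes FAD, and the transporter SLC52A3 had none assigned. Mitochondrial flavoproteins reached 22 of 25 (permutation, adjusted p = 0.053) and were above chance when matched on H3K27ac regions (0.046) and for AhR peaks with a C/EBPα peak, held by 19 of 25 genes (0.028), but not in the 10 kb window (0.15), within 1 kb of a gene end (0.23), with merged peaks only (0.11) or by the mean number of peaks (0.81). The remaining lists that did not pass were sterol synthesis and uptake (16 of 20, permutation, adjusted p = 0.22), the CEBP family (3 of 6, adjusted p = 0.64), stellate cell and fibroblast markers (11 of 16, adjusted p = 0.69), endothelial markers (10 of 13, adjusted p = 0.9) and macrophage and leukocyte markers (9 of 16, adjusted p = 0.9).

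C/EBPα peaks put 7 lists above chance, all of them among the 12 of AhR. The AhR targets were not among these 7, with 11 of 15 genes holding a C/EBPα peak against 65.7% in random lists (permutation, adjusted p = 0.83). By the mean number of peaks, chosen after seeing the data, the AhR targets were above chance for C/EBPα too, with 4.47 peaks per gene against 2.06 (permutation, adjusted p = 0.0085), and the difference between the factors was not tested. Random genes were also matched on the number of H3K27ac regions, with coarser classes of length. Then 6 lists stood above chance for AhR, 5 of the 12 and mitochondrial flavoproteins, and 3 for C/EBPα. For the 12 lists of AhR this matching raised the random share, which left a list less room to stand above it. The permutations treat genes as independent, which neighbouring genes are not.

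**Figure D4:**
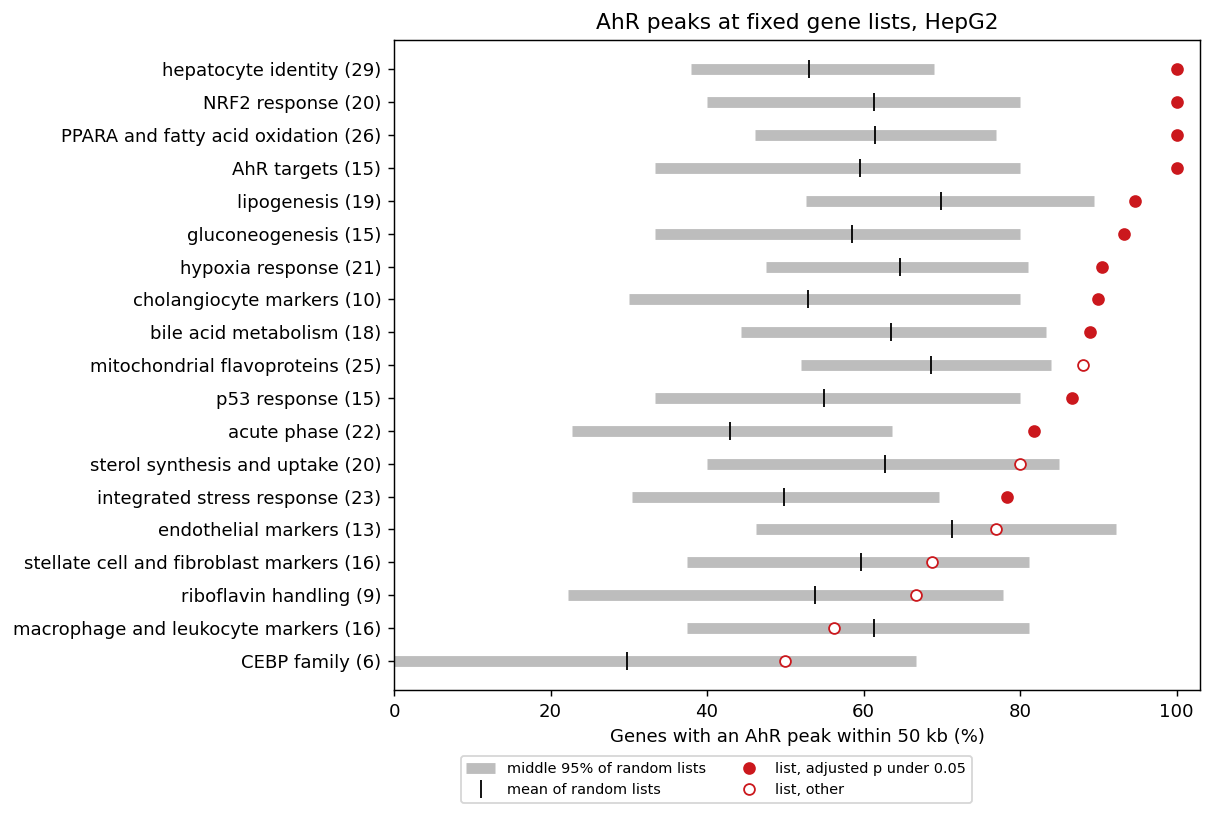
Percent of genes with an AhR peak within 50 kb for which they are the nearest gene (horizontal axis) for the 19 fixed lists in HepG2, with the number of genes found in brackets, the mean and the middle 95% of 10000 length-matched random lists in black and grey, and filled points for an adjusted p under 0.05. The 4 lists at 100% are hepatocyte identity, NRF2 response, PPARA and fatty acid oxidation, and AhR targets.

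The inhibitor experiment asked whether H3K27ac in B2-deficient HepG2 depends on AhR. The list named for that experiment held 97145 regions and the untreated list 106666. Of these, 93202 had identical coordinates in both lists, 95.9% of the inhibitor list and 87.4% of the untreated list. An AhR peak overlapped 39.9% of the shared regions (95% Wilson interval 39.6 to 40.2), 23.2% of the 13464 regions in the untreated list alone (22.5 to 24.0) and 9.36% of the 3943 regions in the inhibitor list alone (8.49 to 10.3). For C/EBPα these shares were 30.6%, 17.2% and 9.51%. The inhibitor list is not divided into vehicle and inhibitor libraries, so these shares do not compare inhibitor with vehicle.

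In mouse liver the AhR list held 41678 peaks with a median width of 250 bp, and the H3K27ac list of floxed hepatocytes held 69615 regions with a median width of 276 bp. An H3K27ac region overlapped 41.5% of liver AhR peaks (95% Wilson interval 41.0 to 41.9), 27.1-fold above random shifts (permutation by shifts, one-sided p = 0.001, the smallest that 1000 shifts can give), from 33.6% on chromosome 7 to 47.6% on chromosome 13. Merged AhR peaks did so in 47.9% and single ones in 36.4%, higher on 20 of 20 chromosomes (11.6 ± 2.78 points, SD over chromosomes, permutation p = 2e-05). An AhR peak lay in 25.1% of the H3K27ac regions. The AhR libraries came from liver and the H3K27ac libraries from hepatocytes with Ad-Cre or Ad-Cont, and the effects of B2 supply and of Cre were not measured in these lists.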

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

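The alternatives with merged peaks alone, the inhibitor list, the union of both lists, peaks beyond 3 kb of gene ends, the mean number of peaks and matching on H3K27ac regions were chosen after seeing the data. Each overlap share moved beyond its counting interval in every alternative run, and these intervals are too narrow. By definition the rule of 50% of the shorter peak can only lower a share, and the union of both lists can only raise it. For the other alternatives the cause was not tested. With an overlap of 50% of the shorter peak the share of AhR peaks with C/EBPα was 54.0%, of AhR peaks with H3K27ac 69.9%, of C/EBPα peaks with H3K27ac 46.4% and of mouse AhR peaks with H3K27ac 39.8%. With centres within 500 bp they were 58.2%, 71.6%, 51.3% and 43.6%, and with both lists restricted to merged peaks only 59.9%, 81.1%, 54.4% and 42.9%. The inhibitor list gave 65.8% for AhR and 45.7% for C/EBPα with H3K27ac, and the union of both lists 71.3% and 49.3%. Since 95.9% of the inhibitor list had coordinates identical to untreated regions, results with it are not an independent check. Beyond 3 kb of gene ends, AhR peaks had C/EBPα in 56.3% and H3K27ac in 77.5%, and C/EBPα peaks had H3K27ac in 54.8%. The odds ratio of AhR and C/EBPα stayed between 9.7 and 11.5 in 4 alternatives, the inhibitor list included.

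The 12 lists above chance for AhR became 12 in the 10 kb window, 8 within 1 kb of a gene end, 11 with merged peaks only, 13 with the mean number of peaks and 6 when matched on H3K27ac regions. Of these, 12, 8, 11, 11 and 5 were among the original 12. By the mean number of peaks, bile acid metabolism was lost (permutation, adjusted p = 0.24) and sterol synthesis and uptake (0.022) and the CEBP family (0.019) were gained. For C/EBPα the 7 lists became 11 in the 10 kb window, 5 within 1 kb of a gene end, 11 with merged peaks only, 11 with the mean number of peaks and 3 when matched on H3K27ac regions, of which 7, 5, 7, 6 and 3 were among the original 7. The cause was not tested. No list fell below chance in any of these settings.

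No paired analysis was possible because the lists carry no values per library. For the same reason other normalizations, count filters, leaving out replicates and a stricter peak score were not run, and GC content and motif alternatives were not run without a genome. Depth is unknown, so what it limits cannot be stated.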

Other observations

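Among genes of at most 20 kb, a class chosen after the values were seen, IRF2BP2, a transcriptional corepressor, had the most AhR peaks with both a C/EBPα peak and an H3K27ac region, 14 of its 26 AhR peaks. FTH1 had 10 of 15, TCIM 10 of 14, TM4SF1 10 of 20, ALB 8 of 24, TAT, a tyrosine-degrading liver enzyme, 8 of 12, and TOB1 8 of 9. CALM2, CCL20, CCN2, CST3, DUSP1, MYC, NEK2 and XBP1 had 7 each. Over genes of any length, WWOX led with 32 of 52. AhR peak density adjusted for gene number and length was 1.22 times higher on chromosomes 2, 14, 16, 17 and 20, grouped from general knowledge of extra copies in HepG2 and not from the sources used here, than on the other 17 autosomes (exact permutation, two-sided p = 0.0028 over 26334 groupings), and the ratio was 1.41 for C/EBPα and 1.56 for H3K27ac. Chromosome 6, outside this group, stood at 1.15, 1.29 and 1.25 times its fitted density for AhR, C/EBPα and H3K27ac. Per gene alone the ratios were 1.03 for AhR (exact permutation p = 0.86), 1.21 for C/EBPα (p = 0.26) and 1.4 for H3K27ac (p = 0.031). In the mouse hepatocyte H3K27ac list, 161 regions lay off the main chromosomes, 159 on 10 unplaced mm10 sequences and 2 on 2 unlocalised ones, and they are included in the overlap shares. The unplaced sequence Un_JH584304 held 101 of them, from position 227 to 106864, which is 0.947 per kb against 0.0287 per kb on autosomes. The mouse liver AhR list had 2 peaks on unplaced sequences, 1 of them on Un_JH584304, and 3 on unlocalised ones.

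The tests for the patterns below were written before their results were seen, except the test for a parent list and the comparison of shared regions with regions of the untreated list alone. The rows for the shared H3K27ac lists were taken out before their results were seen and put back, with the filter rule as first written, after the results were known, so that pattern was chosen for weighing with its results in hand. A rule that also required the C/EBPα share not to fall was tried for the inhibitor after its shares were seen, and was dropped. A weighing of chromosome copies, written after the density had been seen, was set aside, and its values are given above without an explanation.

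HepG2 H3K27ac regions were narrow, with a median of 284 bp against 234 bp for AhR peaks. A candidate explanation is that regions were placed on open or factor-bound sites, and the median centre distance of 28 bp lay under the 75 bp this called for. The alternative that each region is 1 acetylated nucleosome beside a factor-bound gap called for fewer AhR centres within 50 bp of a region centre than at 150 to 250 bp, and the density was instead 53-fold higher there. How the regions were placed is not given in the sources used here, and no biological explanation from the sample groups was tested.

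The HepG2 H3K27ac lists shared most coordinates. That both lists were taken from 1 parent list may account for this, since 0 regions overlapped with other coordinates. Lists merged separately called for more than 0 such regions, so the value argues against separate merging. Weak regions may also have been left out of 1 list by a filter, as the share with an AhR peak was at least 1.72 times lower in regions of 1 list than in shared ones. A biological explanation, that the AhR inhibitor set which regions stayed at AhR-bound sites, met the rule written first, with an AhR peak in 9.36% of regions of the inhibitor list alone against 23.2% of the untreated list alone, while the comparison added later went the other way, with 39.9% in shared regions. Neither decides it, since the list is not divided by treatment and regions of the untreated list alone were also single more often (36.1% against 19.8% of shared ones). A parent list excludes neither the filter nor the inhibitor, and both stay open as to which regions were left out.

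AhR peaks stood above chance at 12 gene lists. Liver-active chromatin rather than the function of a list may set which genes hold AhR peaks, which called for 0 lists left after matching on H3K27ac regions, and at least 6 left would have spoken against it. In all, 5 of the 12 lists stayed above chance, namely AhR targets, PPARA and fatty acid oxidation, NRF2 response, hepatocyte identity and acute phase (adjusted p from 0.0038 to 0.023), so the result fell between the limits set. All but acute phase had a peak at every gene, the highest share possible. The matched random share was 0.842 for gluconeogenesis, 0.828 for lipogenesis and 0.856 for the hypoxia response, which left little room above it. The integrated stress response stood at 0.783 against 0.764. The mean number of peaks was not run with this matching. For the 5 lists that stayed above chance, the number of H3K27ac regions, matched in classes of region number and coarser classes of length, does not account for the whole excess. By the share of genes with an H3K27ac region, PPARA and fatty acid oxidation was itself above chance (permutation, adjusted p = 0.014). AhR targets (0.33), NRF2 response (0.33), hepatocyte identity (0.076) and acute phase (0.3) were not. That number comes from a list with a step 3 kb from gene ends, and APOA1, APOA2 and APOC3 of hepatocyte identity had 0 assigned regions. It may therefore miss part of liver-active chromatin, and that explanation stays open for these 5 lists. It also stays open for gluconeogenesis, lipogenesis, bile acid metabolism, the integrated stress response, the hypoxia response, the p53 response and cholangiocyte markers.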
